A study of Mus musculus with 2 samples.

How the data were processed

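Ebf1-bound regions were mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in mature 3T3-L1 adipocytes, a mouse fibroblast line that turns into fat-storing cells when given a hormonal mixture. Per the labels' protocols, the cells were fixed with 1% formaldehyde 10 days after the mixture known as MDI was added. Chromatin was precipitated with a commercial antibody against Ebf1, ligation products of 275 to 700 bp were cut from a gel, and the libraries went through 18 cycles of PCR. The labels describe 2 libraries, 1 Ebf1 ChIP and 1 whole cell extract made without antibody. The processed data used here are the peak list of the Ebf1 library. No values of the whole cell extract were analysed here, so no comparison between libraries was possible and there are no replicates.

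Per the submitters' processing notes, the genome build was mm9 and SAMtools was among the tools. The aligner, the peak caller, its threshold, any read filter and the way the whole cell extract entered the calling are not given in the sources used here. The deposited list has no header. It gives a position for each peak and 2 whole-number columns whose meaning is not stated. The deposited score used here is the first of these columns, which ranged from 3 to 597. The deposited score in the other column, called the second value below, ranged from 0 to 15. The lowest score among peaks rose from 3 at a second value of 0 to 7 at a second value of 4 and 11 at a second value of 6. Neither column is treated as a read count. Another 2 columns held 1 and 0 in every line. Only the first whole-number column was used to rank peaks. No read depth is given, so the depth behind each peak is unknown.

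All 34534 starts lay 1 base past a multiple of 25 and all ends on a multiple of 25, so positions were read as 1-based with both ends included, and were neither shifted nor converted. Peak width is the end minus the start plus 1. The gene table at hand belongs to GRCm38, another build, so it was not used to place genes, and no mm9 sequence or gene annotation was used here. For this reason 5 planned analyses were not run. These were the position of peaks relative to genes, the Ebf motif in peaks, other motifs in peaks, gene lists near peaks, and the split of scores by location and motif. Regions are therefore given by coordinates.

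Peaks per Mb were computed for chromosomes 1 to 19 and X over the span from the first to the last peak, with an exact Poisson 95% interval that covers counting error only. Neighbouring peaks cluster, so these intervals are too narrow, and no test between chromosomes was planned without chromosome sequences. Clustering was tested on chromosomes 1 to 19, X and Y by placing the same number of peaks uniformly within each chromosome's span 100 times. Each one-sided p counts the placements at least as clustered as the data, and the smallest that 100 placements can give is 0.0099. Gaps in the assembly could not be left out of these spans. Clusters were formed by joining peaks whose centres lay within 12.5 kb of the next. The relation of score to width was given as Pearson's r and Spearman's rho across peaks with two-sided permutation p from 100000 resamples. Every test describes this one list. Peaks are not replicates, and the spread between cultures is unknown. Shares carry exact Clopper-Pearson 95% intervals for counting error only.

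Before the data were examined, the designs, the alternatives and the rule for naming regions were fixed. That rule names genes where genes can be placed, and otherwise the 10 peaks with the highest score and the 5 clusters with the most peaks. The alternatives were peaks at or above the median score of 13, the top 10% by score (a score of 55 or more), merging of touching peaks, and joining distances of 5 and 25 kb. Full chromosome length was another, and could not be run without chromosome sequences. The design itself set peaks per Mb over the sequenced length. Without a usable reference it set the span from the first to the last peak, which was used here. Leaving out 1 Mb windows with 50 or more peaks was added after seeing the data, alone or together with the median score threshold. On simulated positions for the 34189 placed peaks, the clustering test returned a ratio of 1.01 to random for uniform placement. It returned 1.82 when 40% of peaks were planted as pairs within 5 kb. A correlation of 0.3 simulated in 2000 pairs was recovered as 0.321. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.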

Results

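Binding of Ebf1, a helix-loop-helix transcription factor known for its part in B cell and adipocyte development, was profiled in mature 3T3-L1 adipocytes to find the regions it occupies in fat cells. The list from the 1 Ebf1 ChIP library held 34534 peaks on the mm9 genome. Of these, 34156 lay on chromosomes 1 to 19 and X, 33 lay on chromosome Y, and 345 lay on 11 unplaced sequences. Peaks covered 11.9 Mb in all. None overlapped or touched another, and the closest pair was separated by 25 bp. The median width was 300 bp, with quartiles of 225 and 425 bp and a range of 200 to 975 bp. The narrowest width, 200 bp, was shared by 7001 peaks or 20.3% of the list. With 1 library and no values from the whole cell extract, none of the values below has a replicate error.

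Peak scores were strongly skewed. Strong and weak refer below to this score alone, whose meaning is not stated. The median score was 13, with quartiles of 8 and 26, and the highest was 597. The 3515 peaks with a score of 55 or more, 10.2% of the list, carried 41.3% of the summed score. A score of 100 or more was reached by 1214 peaks.

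The 10 strongest Ebf1 peaks scored between 348 and 597 and lay on 8 autosomes. The strongest covered chromosome 17 from 4625901 to 4626800. Its score of 597 was 45.9 times the median, and no other peak lay within the joining distance used for clusters. The next, on chromosome 13 from 113842426 to 113843300, scored 441 and also stood alone. The third, on chromosome 2 from 118355026 to 118355850, scored 426 and belonged to a cluster of 3 peaks. The peak on chromosome 6 from 87051201 to 87052075 scored 419, and the one on chromosome 7 from 105816351 to 105817275 scored 389. Each of these had 1 neighbour in its cluster. Chromosome 5 held a peak with a score of 386 from 36052851 to 36053575, in a cluster of 4. It held another with a score of 367 from 118944976 to 118945800, in a cluster of 6. The peak on chromosome 8 from 19707076 to 19707775 scored 370 and was 1 of 15 in its cluster. Its second value of 11 was the highest of the 10. A second strong site on chromosome 6, from 55238001 to 55238875, scored 359 within a cluster of 11 peaks. The last, on chromosome 1 from 154969626 to 154970400, scored 348 in a cluster of 5. These 10 peaks were 700 to 925 bp wide. Chromosome X held none of them. Its strongest peak, from 9639101 to 9639750, scored 172. Which genes these regions lie in or near was not analysed here, because no mm9 annotation was used.

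Whether Ebf1 peaks followed chromosome length was examined next. They did not spread evenly. The median autosome held 12.3 peaks per Mb. Chromosome 19 was densest, with 21.3 peaks per Mb (95% interval 20.2 to 22.6), followed by chromosome 2 with 19.8 (19.2 to 20.5), chromosome 8 with 19.3 (18.6 to 20.1), chromosome 17 with 18.6 (17.7 to 19.5) and chromosome 6 with 18.5 (17.9 to 19.3). The sparsest autosome was chromosome 14, with 8.21 peaks per Mb (7.70 to 8.73), so the densest and sparsest autosomes differed by 2.60 times. The order below chromosome 19 changed with the score threshold. Chromosome 11, at 1.37 times the median autosome for all peaks, came second at or above the median score with 1.46 times. It was ahead of chromosome 8 at 1.39 and chromosome 2 at 1.37. Chromosome 6 fell from 1.51 to 1.18 at that threshold, but was at 1.46 in the top 10% by score. Without 1 Mb windows of 50 or more peaks, a setting chosen after seeing the data, chromosome 2 held 1.39 times the peaks per Mb of the median autosome, below chromosomes 17 at 1.46, 6 at 1.43 and 8 at 1.41. Chromosome X held 4.92 peaks per Mb (4.59 to 5.27), which was 0.401 of the median autosome. The intervals of 9 autosomes lay wholly above the median autosome and those of 8 wholly below it. These intervals cover counting error only. Within chromosomes the counts per 1 Mb window varied widely, with 19.8 ± 22.4 peaks (SD, n = 179 windows) on chromosome 2, 21.0 ± 14.5 (SD, n = 59 windows) on chromosome 19 and 4.90 ± 7.88 (SD, n = 164 windows) on chromosome X.

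Strong peaks were also unevenly spread. Peaks with a score of 55 or more numbered 0.823 per Mb on chromosome 14, 1.36 on the median autosome, 2.12 on chromosome 11 and 2.32 on chromosome 19. Chromosome X held 0.257 per Mb, or 0.189 of the median autosome. Of the peaks on X, 5.22% (exact 95% interval 3.79 to 7.0) reached that score, against 10.4% of autosomal peaks (Fisher's exact test, two-sided, p = 3.6e-07, counting peaks as independent). This test was added after seeing the data. On X, the 1 Mb windows from 4 to 5 and 92 to 93 Mb held 59 and 54 of its 804 peaks, none of them strong. On chromosome 2 the excess over the median autosome fell from 1.61 times for all peaks to 1.30 times for strong ones, and its 1 Mb windows from 175 to 178 Mb held 460 peaks, none of them strong.

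**Figure D1:**
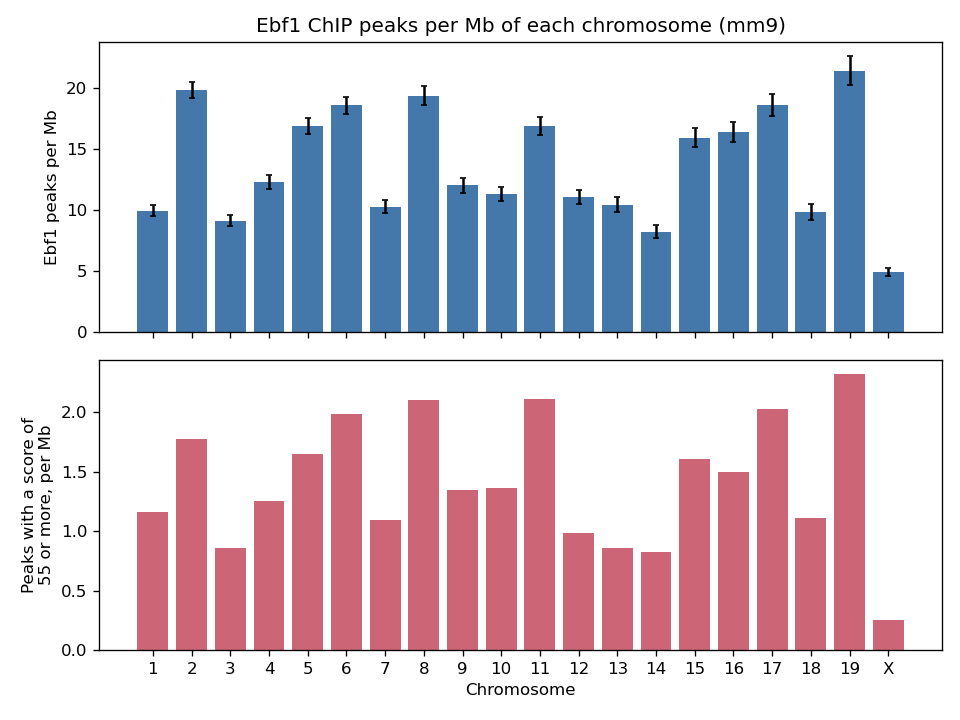
Ebf1 peaks per Mb of the span between the first and last peak on chromosomes 1 to 19 and X, for all peaks (upper panel, error bars are exact Poisson 95% intervals) and for peaks with a score of 55 or more (lower panel, no error drawn). Chromosome 19 is highest in both panels, at 21.3 and 2.32 per Mb, and chromosome X is lowest in both, at 4.92 and 0.257 per Mb.

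**Figure D2:**
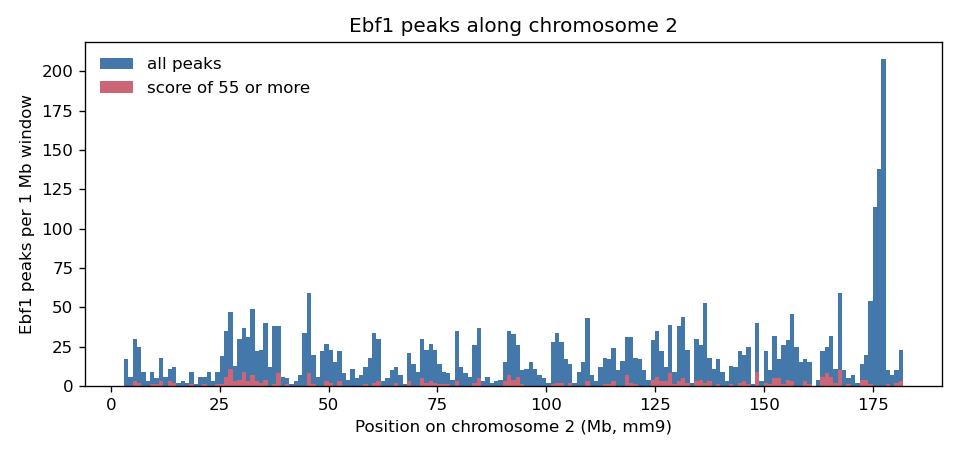
Ebf1 peaks in each 1 Mb window of chromosome 2 (x axis, position in Mb on mm9; y axis, number of peaks), for all peaks and, in front, for peaks with a score of 55 or more. The tallest window, from 177 to 178 Mb, holds 208 peaks, none of which has a score of 55 or more.

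Ebf1 peaks lay closer together than uniform random placement gave over the spans, which include assembly gaps and unmappable sequence. Of the 34189 peaks on placed chromosomes, 19118 or 55.9% had another peak centre within that joining distance. Random placements gave 10413 ± 117 such peaks (SD over 100 placements) and at most 10720, so the observed number was 1.84 times the random mean (n = 34189 peaks, one-sided p = 0.0099, the smallest that 100 placements can give). The median distance between neighbouring centres was 22113 bp, against 48290 ± 325 bp (SD over 100 placements) at random (n = 34189 peaks, one-sided p = 0.0099). Among peaks with a score of 55 or more the same count was 5.15 times that of random placement. A shorter list gives fewer random neighbours, so this ratio cannot be set against 1.84. The median distance was 0.426 of the random one among these peaks and 0.458 for all peaks. Joining peaks gave 6338 clusters of at least 2 peaks and left 15071 peaks alone. There were 92 clusters of 10 or more peaks, which held 1416 peaks.

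The 5 clusters with the most peaks lay on chromosomes 2, 8 and X. The largest, on chromosome 2 from 176889926 to 177096100, held 70 peaks over 206 kb, with a median score of 13 and none above 45. The densest of the 5 was on chromosome X from 92119251 to 92175300, where 53 peaks filled 56.1 kb at 9.46 peaks per 10 kb, with none above a score of 36. The next 2, on chromosome 2 from 177292351 to 177397400 and from 177478176 to 177605150, held 41 peaks each, with highest scores of 37 and 35. The fifth, on chromosome 8 from 71344876 to 71430075, held 37 peaks over 85.2 kb. It was unlike the others in score: 5 of its peaks reached 55 or more, and the highest was 253. The size of the largest cluster followed the joining distance, with 53 peaks at 5 kb and 187 at 25 kb. With fewer peaks in the list it was smaller by construction, at 32 peaks at or above the median score, 6 in the top 10%, 20 without 1 Mb windows of 50 or more peaks and 13 with that setting and the median score threshold together.

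Ebf1 peaks with a higher score were wider. The score may follow width through the way the caller computes it, so this relation describes the list and not binding. The lowest score also rose with width, from 3 at 200 bp to 16 at 500 bp. The median score was 7 at a width of 200 bp, 12 at 300 bp, 40 at 500 bp and 88.5 at 700 bp. Across the 34534 peaks, which are not independent replicates, Pearson's r between score and width was 0.812 and Spearman's rho was 0.925 (permutation test, p = 1e-05 for each, the smallest that 100000 resamples can give). In all, 6 correlations of score with width were computed, over the whole list and above 2 score thresholds, each with this p, so the Benjamini-Hochberg adjusted values are the same. At widths over 800 bp the median score levelled between 117 and 153. The widths ended at 975 bp, with 30 peaks there and none wider, and whether the calling set a limit is not given. Among peaks with a score of 55 or more, a list cut on the score itself, r was 0.526 and rho 0.555.

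**Figure D3:**
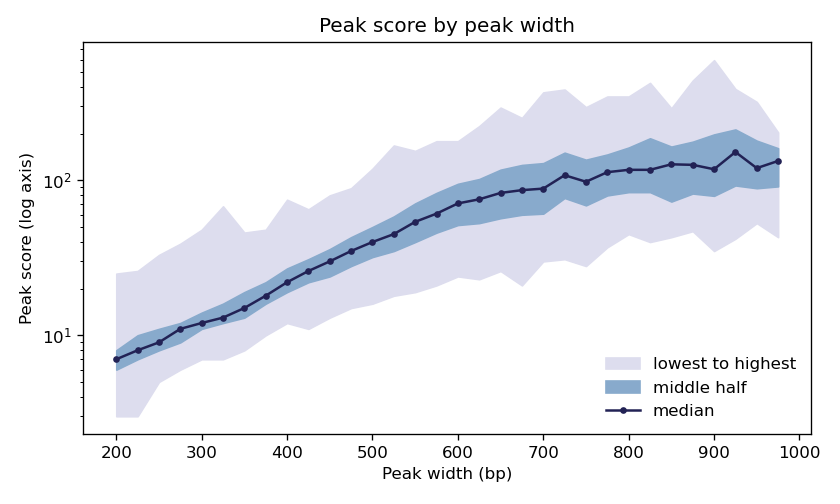
Peak score on a log axis against peak width in bp for the Ebf1 list. The line is the median at each width, the inner band runs from the lower to the upper quartile and the outer band the lowest to the highest score, and the median rises from 7 at 200 bp to 88.5 at 700 bp.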

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

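The tests in this part were chosen after the values had been seen. Peaks on sequences outside the main comparisons drew attention first. The 345 peaks on unplaced sequences included 125 on chr8_random and 99 on chr1_random, and 10 of the 345 had a score of 55 or more. The strongest lay on chr1_random from 272226 to 273150, with a score of 297. The second value, which ranks no peak in the comparisons above, was above 0 at 24236 peaks.

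The second value was 0 for all 378 peaks on unplaced sequences and chromosome Y together, against 29.0% of peaks on chromosomes 1 to 19 and X. If peaks there had zeros as often as peaks of the same width elsewhere, 111 would be expected, and the highest of 10000 draws was 140, which argues against so many zeros by chance, whatever the column measures. The 68 peaks of 500 bp or more were all at 0, where 5.16 were expected. A candidate explanation is that the second value was not measured on these sequences, which stays undecided, since the 378 zeros are the pattern itself and no other value bears on it. No biological explanation was tested.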

How the results depend on the processing

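Of 84 alternative values, 40 counted as unmoved, 44 moved and none reversed direction. For tested results unmoved means the same direction and the same side of the 0.05 threshold, whatever the size of the effect. For counts and covered length it means within 1.5 times, and for chromosomes within the Poisson 95% interval of the chromosome's own count in the full list. That interval is too narrow for shorter lists, and which autosome is the median changes with the setting. Some chromosomes may therefore count as moved through counting error or the change of reference. Clustering stayed past its threshold in all 10 alternatives of the neighbour count and the median distance. All of them used uniform placement over spans that include assembly gaps and unmappable sequence, so they do not test that choice. The neighbour count was 2.65 times random at or above the median score, 5.15 in the top 10%, 2.65 with a 5 kb and 1.41 with a 25 kb joining distance, and 1.89 without 1 Mb windows of 50 or more peaks, where random positions could still fall in those windows. These ratios depend on the length of the list and the joining distance. The median distance was 0.458 of random as deposited, 0.386 at or above the median score, 0.426 in the top 10% and 0.466 without the dense windows. The correlations of score with width stayed positive but fell, r from 0.812 to 0.774 at or above the median score and 0.526 in the top 10%, and rho from 0.925 to 0.892 and 0.555. These lists were cut on the score itself, which narrows its range and can by itself lower the correlations. Their permutation p was the smallest possible throughout, so it shows no change in strength. At or above the median score 17479 peaks covering 7.90 Mb remained, by construction, and merging changed nothing. Chromosome X fell from 0.401 of the median autosome to 0.309 at or above the median score, 0.189 in the top 10% and 0.357 without the dense windows. Chromosome 19 went from 1.74 to 1.56 times at or above the median score, and chromosome 14 from 0.668 to 0.601 there and 0.604 in the top 10%. The cause was not tested. The dense windows were left out by a choice made after seeing the data. Full chromosome lengths, genomic location, motifs, gene lists and the split of scores by location or motif were planned and not run, as no mm9 sequence or annotation was used. No replicate could be left out with 1 library, and no paired analysis was possible because the whole cell extract had no values here. The depth of the library is unknown, so weak peaks cannot be told from chance calls.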

Other observations

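The tests in this part were chosen after the values had been seen. Where they concern background, they assume that the second value measures it, which no source used here states. Most Ebf1 peaks, 31704 of 34156 on chromosomes 1 to 19 and X, lay in 1 Mb windows of under 50 peaks, and the median window with a peak held 10. Of 2586 windows, 35 held 50 or more peaks. In 9 of these 35 windows no peak reached a score of 55. They lay at 175 to 178 Mb on chromosome 2, 145 to 147 Mb on chromosome 4, 65 to 67 Mb on chromosome 13, and 4 to 5 and 92 to 93 Mb on chromosome X, and together held 946 peaks. Over all 31 windows of 50 to 99 peaks, 11.4% of peaks (exact 95% interval 9.94 to 12.9) reached that score, against 10.4% in windows of under 50 peaks, and single windows varied. Of those picked after their values were seen, the window from 84 to 85 Mb on chromosome 17 held 75 peaks, 18 of them at 55 or more, and the one from 136 to 137 Mb on chromosome 5 held 56, of which 14 were. The low end of the 31 windows was 0. None reached it of 86 peaks at 145 to 146 Mb on chromosome 4, or of 85 at 66 to 67 Mb on chromosome 13. The same held for 69 peaks at 65 to 66 Mb on chromosome 13, and for 59 and 54 in the 2 windows on chromosome X. Above these, 1 of 54 peaks from 174 to 175 Mb and 2 of 53 from 136 to 137 Mb on chromosome 2 reached it.

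Ranked by summed score, the cluster at 71344876 to 71430075 on chromosome 8 came first with 1200, followed by the cluster with the most peaks, at 176889926 to 177096100 on chromosome 2, with 1071. On chromosome 16 from 32656601 to 32689225, only 8 peaks summed to 851, with a median score of 59.5 and a highest score of 289. A cluster on chromosome 6 from 94865601 to 94917975 held 14 peaks with a summed score of 832. At the other extreme, no peak was listed on chromosome 7 between 39332425 and 46441376, a gap of 7.11 Mb, where the longest gap in 100 random placements was 2.29 Mb. There were 34 gaps over 2 Mb, 13 of them on chromosome X. Assembly gaps and unmappable sequence were not left out of these spans.

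The 4 windows of 100 or more peaks, 3 on chromosome 2 and 1 on chromosome 4, held 593 peaks and none with a score of 55 or more (exact 95% upper limit 0.620%, for counting error only), against 10.4% in windows of under 50 peaks, but 3 of the 4 are adjacent and the difference was not tested. The second value of peaks was 1.56 times (bootstrap 95% interval 1.47 to 1.66) that of peaks of the same width in windows of under 50 peaks, but it was also 1.31 times (1.27 to 1.36) in windows of 50 to 99 peaks. Neither interval covers the spread between windows. Single windows ranged from 1.23 to 1.97 times among the 4 and from 0.927 to 2.76 times among those of 50 to 99 peaks. Of the 4 windows, 3 were raised 1.23 to 1.49 times. The highest of these 3 was matched or exceeded by 7 windows of 50 to 99 peaks. In these 7, 9.61% of peaks (bootstrap over windows, 95% interval 4.02 to 15.2) reached a score of 55. The fewest were 0 of 59 peaks at 4 to 5 Mb on chromosome X and 1 of 54 at 174 to 175 Mb on chromosome 2. The most were 14 of 56 at 136 to 137 Mb on chromosome 5. Further windows of 50 to 99 peaks matched or exceeded only the lower ratios, and their pooled share was not computed. They ranged from 0 of 86 peaks at 145 to 146 Mb on chromosome 4 to 11 of 58 at 94 to 95 Mb on chromosome 6. Whether higher background is the whole cause cannot be decided from the 7 windows, because they were picked by their second value. Over all peaks the median score rose from 10 at a second value of 0 to 44 at 5. Widths were not matched there, as they were in the pick, so whether the pick favours windows with strong peaks is not known. For the window from 177 to 178 Mb on chromosome 2, raised 1.97 times, higher background cannot be told apart either, because only 1 other dense window was raised as much, with 5.88% such peaks. Sequence present in more copies in the cells than in mm9 may give such a pattern, but no sequence was searched and no biological explanation was tested.

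The uneven density of peaks between chromosomes was set against the second value. Over chromosomes 1 to 19 and X, the mean second value of 200 bp peaks rose with peaks per Mb (Pearson's r = 0.812, permutation p = 2.0e-05, and Spearman's rho = 0.788, permutation p = 6.0e-05). Without chromosomes 2 and 19, the 2 farthest from the median density, r was 0.795 (permutation p = 6.0e-05), so a background that differs between chromosomes may, if the second value measures it, account for part of the differences. A few very dense windows are argued against as the whole cause, since the CV between chromosomes was 0.338 with them and 0.322 (bootstrap 95% interval 0.289 to 0.357) without windows of 50 or more peaks. Whole-chromosome copy number cannot be told apart from local background, because the second value also followed the peak count of windows within chromosomes (r = 0.263 over 1107 windows, bootstrap 95% interval 0.217 to 0.309); gene content and more Ebf1 sites on some chromosomes were not tested.

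The list was not in order of position. On 24 sequences it consisted of up to 5 separately sorted runs, and the 744 peaks ahead of the last run had a mean score of 35.2, against 24.0 for the rest (permutation test, two-sided, p = 0.0001, the smallest that 10000 draws can give). Their median widths were 375 and 300 bp.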
